A study of Rattus norvegicus with 34 samples.

How the data were processed

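Gene expression was measured in RNA of primary rat cortical neurons kept in culture for 21 days, on 34 arrays of the Illumina RatRef-12 V1 bead platform. Per the labels' protocols, biotin-labelled RNA was hybridised, cortices came from Hooded Wistar embryos, at least 12 wells were pooled for each time point, and 3 cultures from different pregnant rats were used. The labels do not tie a replicate number to a culture. Per the labels' protocols, axon bundles were injured either by transection with a knife or by stretch with puffs of oxygen, and no label says which of these was the mild and which the severe injury. The array barcodes in the labels placed the arrays on 4 chips of up to 12 arrays.

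The authors deposited one linear ratio per probe and array. The divisor was found from the values: of all 5984 possible triples of arrays, 2 averaged 1 at all 22226 probes within 1e-04. One triple carried the labels control replicates 1 to 3 and divided 18 arrays (6 control, and mild 0, 8, 15 and 24 h). The other triple carried the labels mild 48 h replicates 1 to 3 and divided 16 arrays (mild 48 h and every severe array). Setting the columns of the 2 deposited tables against each other, without giving any column a sample, showed each ratio to be an array's signal over that array's median, divided per probe by the mean of the 3 arrays named. Background correction, software and filters were not stated in the deposited tables. The deposited table of scanner signals holds 34 columns of per-sample values whose names match no sample's labels. None of these columns entered a comparison. The 2 tables hold the arrays in different orders: in the signal table, the columns whose values match the arrays labelled mild 48 h stand directly after those matching control 1 to 3 and before those matching control 4 to 6 and mild 0 to 24 h. Labels given in the other order would put 18 arrays (those labelled mild 48 h, control 4 to 6 and mild 0, 8, 15 and 24 h) in other groups. In that order, the arrays labelled mild 48 h would be control 4 to 6, and those labelled control 4 to 6 would be mild 0 h. Those labelled mild 0, 8, 15 and 24 h would be mild 8, 15, 24 and 48 h. The severe arrays would then be divided by, and compared with, controls. The series design, in which 6 controls serve every injury, goes with that order but does not settle it. These group names, and the chips of the 18 arrays, therefore follow the deposited labels. The description column of the signal table served only to name probes. The smallest ratio was exactly 0.01 and occurred 3 times, among them for Tnmd in severe 48 h replicate 3 and Lum in severe 8 h replicate 1, so it may be a floor set before deposition, and these values were kept. Ratios carry no signal level, so detection and signal over background are unknown, and the number of arrays limits the precision.

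Ratios were put on the log2 scale and used as deposited. Probe names came from the platform annotation for 13192 probes, from the RefSeq accession for 363 and from the deposited description for 8563, and 108 probes had no name. Probes of the 321 genes with several probes were averaged, which gave 21789 genes and 21897 tested features in all. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests, 1 mean per group), with Benjamini-Hochberg adjustment within each comparison and a threshold of adjusted p under 0.05. Differences are log2 differences, injured minus reference, with their standard error. The p-values measure only the spread between these arrays. The 25 gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with a correlation estimated for each list, adjusted over the 25 lists. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

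The groups, the tests, the 25 gene lists, the rule for named genes and a first set of alternatives were chosen before the data were examined. That design assumed scanner signals with background correction, quantile normalization, a detection filter and 1 probe per gene. With ratios the first 3 steps could not be done or were left out, and probes were averaged. Because the 2 sets of arrays have different divisors, the following planned comparisons were left out: mild 48 h against control, severe against control at any time, severe against mild at 8, 15 and 24 h, and the 3 planned averages over times with their list tests. The mild time course was tested over 0, 8, 15 and 24 h, and the change of the severe by mild difference over 8, 15 and 24 h, where a divisor common to all times of an injury cancels. Planned comparisons were fitted on all 34 arrays with 1 spread. Chosen after seeing the data were the comparisons of severe arrays at 8, 15 and 24 h, and of their average with 48 h, against the arrays labelled mild 48 h, the severe time course, and the comparisons of control 4 to 6 and of the mild arrays with control 1 to 3. These were fitted on the 18 or 16 arrays of 1 divisor. Controls were split by their place in the divisor, not by an outcome.

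Named genes followed a rule. For the average comparison these were the 10 largest rises and the 10 largest falls among genes past the threshold with and without the chip as a block. For single times and the tests over several times they were the 3 largest each way, filled where needed with genes past only without the block. For each list they were up to 4 members with the smallest adjusted p. Symbols starting with LOC, RGD or MGC were not named, and 3 genes that the rule takes are not reported here. Alternatives were the chip as a block, the replicate number as a block, only the arrays of the compared groups, only the arrays of 1 divisor or all arrays, comparisons within a chip, quantile normalization of the ratios within each set, centring on 146 housekeeping genes (the ribosomal, proteasome and oxidative phosphorylation lists), the housekeeping median as a covariate, and leaving out each array in turn.

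The fits were tested on simulated data made from the real spread, with 50 genes changed at each fold. In the layout of mild 8 h against control, limma recovered 70% of genes changed 1.5-fold and 96% of those changed 2-fold, with 10 false calls. In the layout of the severe average, it recovered 70% and 92%, with 9 false calls. The simulated noise was independent between genes and arrays, without shifts shared by an array, a chip or a culture. These rates therefore need not hold for the real arrays.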

Results

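Expression of 21789 genes was measured on 34 arrays of cultured rat cortical neurons: 6 control arrays, 3 arrays at each of 0, 8, 15, 24 and 48 h after mild neurotrauma, 3 at each of 8, 15, 24 and 48 h after severe neurotrauma, and 1 at severe 0 h. The values were ratios to the mean of 3 arrays, control 1 to 3 for the control and mild 0 to 24 h arrays, and the arrays labelled mild 48 h for those arrays and all severe arrays. The SD of the log2 ratios over genes was 0.45 to 0.60 in the severe arrays and 0.09 to 0.25 in the control and mild 0 to 24 h arrays. It was 0.07 to 0.09 in the 3 arrays labelled mild 48 h. These arrays and control 1 to 3 (0.09 to 0.12) are part of their own divisor, which keeps their SD small. The 2 sets have different divisors, so their SDs are not a like measure of spread. The median log2 ratio of 146 housekeeping genes (ribosomal, proteasome and oxidative phosphorylation genes) was between -0.20 and 0.43 in the control and mild 0 to 24 h arrays. It was between -0.19 and 0.13 in all severe arrays but severe 48 h replicate 2, at -0.77. The 2 deposited tables order the arrays labelled mild 48 h, control 4 to 6 and mild 0, 8, 15 and 24 h differently, so the labels of these 18 arrays are uncertain, and their groups are named here as labelled. In the other order the arrays labelled mild 48 h would be control 4 to 6, and those labelled control 4 to 6 would be mild 0 h. The severe comparisons would then be against controls. The number of arrays limits the precision of every value.

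**Figure D1:**
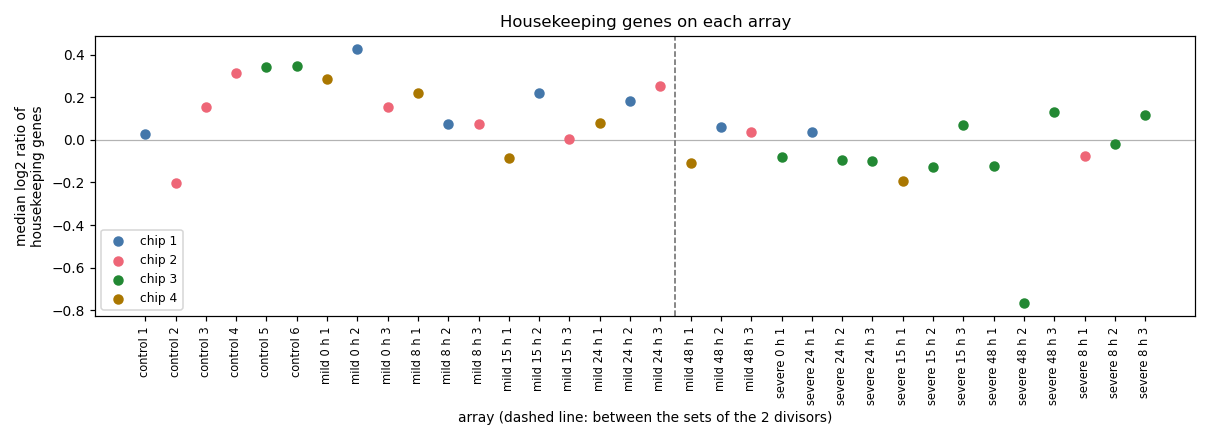
Median log2 ratio of the 146 housekeeping genes (vertical axis) in each of the 34 arrays (horizontal axis, group and replicate), 1 point per array, coloured by chip, with a dashed line between the sets with different divisors. Severe 48 h replicate 2 lies at -0.77, and control 4 to 6 lie at 0.31 to 0.35 against -0.20 to 0.15 for control 1 to 3.

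The arrays labelled severe 48 h were set against those labelled mild 48 h, the only severe and mild arrays of 1 time with a common divisor, with 3 arrays each, all differences being severe minus mild on the log2 scale with the SE. Dynlrb2, a dynein light chain, rose by 4.50 ± 0.31 (22.7-fold, adjusted p = 2.13e-11), and Cfap126, a protein of motile cilia, by 4.21 ± 0.35. The largest falls were those of Tnmd, a tendon marker, at -5.56 ± 0.48 (adjusted p = 1.41e-09), Aspn, a matrix proteoglycan, at -5.31 ± 0.47, and Col14a1, a collagen, at -4.88 ± 0.26. The ratio of Tnmd in severe 48 h replicate 3 was 0.01, the smallest value of the table and possibly a floor. Each of these 5 genes lay beyond all mild 48 h arrays in 3 of 3 severe arrays, which their choice as the largest changes makes likely. limma passed 3731 of 21897 features, 1260 higher and 2471 lower (5826 at an unadjusted p under 0.05), and 3292 with the chip as a block (923 higher and 2369 lower, 2984 shared). Centring on the housekeeping genes moved the median of all genes from 0.00 to 0.25 and passed 3749, with 2275 higher and 1474 lower. The ribosomal genes among them fell at 48 h themselves, so this split is no independent check of direction. Without severe 48 h replicate 2, whose housekeeping median was -0.77, limma passed 3447, with 1817 higher and 1630 lower. No array labelled mild 48 h shares a chip with a severe 48 h array, so no comparison within a chip was possible. The fit with the chip as a block takes the chip differences from other groups. These include the controls, fitted as 1 group, so its count is a weak check of the chip. If the labels of the reference arrays are displaced, this is not a comparison of 2 injuries at 1 time. limma passed 1481 with only the compared arrays fitted, 2157 with quantile normalization and 2453 with the 16 arrays of 1 divisor.

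By list at 48 h, the fibroblast and meningeal genes, which build collagen-rich matrix, fell in 14 of 19 members and rose in 0, or 14 fallen and 1 risen adjusted over the list alone, with Col1a1 (-4.30 ± 0.34) and Col6a1 (-3.43 ± 0.18). It was the only list past the threshold with both correlations, in the 11 comparisons with list tests (median -2.60, camera adjusted p = 6.84e-13; adjusted p = 0.0438 with an estimated correlation). Ribosomal protein genes fell in 54 of 63 members, 55 adjusted over the list alone (median -0.89, camera adjusted p = 5.89e-30; adjusted p = 0.152 with an estimated correlation). Rps2 (-1.54 ± 0.15) was among these genes. Genes of the unfolded protein and integrated stress responses fell in 21 of 38 and rose in 1 (22 and 1 adjusted over the list alone), among them the ATF4 targets Trib3 (-2.53 ± 0.10), Asns (-1.61 ± 0.17) and Ddit3 (-1.45 ± 0.14) (median -0.66, camera adjusted p = 4.64e-10; adjusted p = 0.152 with an estimated correlation). Hypoxia and glycolysis genes fell in 19 of 33 and rose in 3 (20 and 3 adjusted over the list alone, median -0.56, camera adjusted p = 4.03e-09; adjusted p = 0.16 with an estimated correlation). The lactate carrier Slc16a3 (-3.31 ± 0.20) and pyruvate kinase Pkm (-2.10 ± 0.18) were among these genes. Without severe 48 h replicate 2, the medians were -2.31 for the fibroblast, -0.69 for the ribosomal, -0.41 for the stress response and -0.31 for the hypoxia list.

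Glial and interferon genes at 48 h went the other way. Oligodendrocyte lineage genes rose in 12 of 19 members and fell in 1 (12 and 2 adjusted over the list alone, median 1.03, camera adjusted p = 1.47e-08; adjusted p = 0.152 with an estimated correlation). The myelin genes Mal (2.18 ± 0.18) and Ugt8 (2.15 ± 0.28) were among these genes. Astrocyte genes rose in 11 of 24, 13 adjusted over the list alone (median 0.51, camera adjusted p = 6.71e-11; adjusted p = 0.152 with an estimated correlation). S100b (3.10 ± 0.25) and Mlc1 (2.22 ± 0.22) were among these genes. Interferon and antigen presentation genes rose in 19 of 34, 25 adjusted over the list alone (median 0.58, camera adjusted p = 6.84e-13; adjusted p = 0.152 with an estimated correlation). The induced GTPase Gbp2 (3.69 ± 0.26) and the immunoproteasome subunit Psmb8 (1.58 ± 0.22) were among these genes. Antioxidant and NRF2 targets rose in 8 of 38 and fell in 1 (12 and 4 adjusted over the list alone, median 0.13, camera adjusted p = 0.002; adjusted p = 0.575 with an estimated correlation). The glutathione transferase Gstm1 (2.46 ± 0.23) was among these genes. Without severe 48 h replicate 2, the medians were 1.04 for the oligodendrocyte, 0.63 for the astrocyte, 0.69 for the interferon and 0.38 for the NRF2 list.

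Further lists past the threshold at 48 h included axonal cytoskeleton and transport genes, which fell in 16 of 39 (16 adjusted over the list alone, median -0.49, camera adjusted p = 0.000117; adjusted p = 0.575 with an estimated correlation). Tubb2b (-1.20 ± 0.16) was among these genes. Their median was -0.13 without severe 48 h replicate 2. Cholesterol synthesis genes fell in 8 of 29 and rose in 1 (8 and 1 adjusted over the list alone) (median -0.55, camera adjusted p = 0.00146; adjusted p = 0.606 with an estimated correlation), and their median was -0.22 without that array. Matrix genes fell in 16 of 35 and rose in 3 (16 and 5 adjusted over the list alone), with the protease Adamts1 (-2.79 ± 0.16) and the crosslinking enzyme Lox (-2.63 ± 0.31) (median -0.33, camera adjusted p = 0.00164; adjusted p = 0.288 with an estimated correlation; median -0.13 without that array). Immediate early genes fell in 10 of 31, 11 adjusted over the list alone (median -0.21, camera adjusted p = 0.0015; adjusted p = 0.541 with an estimated correlation). Klf2 (-1.71 ± 0.10) and Sik1 (-1.61 ± 0.27) were among these genes. The list's median was -0.04 without that array and 0.04 with housekeeping centring, and its camera adjusted p was 0.0819 with the chip as a block. Calcium handling genes fell in 8 of 32 and rose in 2 (10 and 2 adjusted over the list alone), although the calcium buffer Calb1 (2.51 ± 0.28) was among those that rose (median -0.33, camera adjusted p = 0.00616; adjusted p = 0.598 with an estimated correlation; adjusted p = 0.0671 at the preset correlation without that array, median -0.06). Neurotrophic factor genes fell in 10 of 36 and rose in 1 (12 and 1 adjusted over the list alone; median -0.05, camera adjusted p = 0.0306; adjusted p = 0.288 with an estimated correlation), with a median of 0.20 under housekeeping centring and an adjusted p of 0.0543 without that array. Without that array, the preset correlation also put 3 lists past the threshold upward: oxidative phosphorylation (median 0.15), proteasome (0.22) and heat shock chaperones (0.02).

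Across 8, 15, 24 and 48 h, the 12 severe arrays averaged over times were set against the 3 arrays labelled mild 48 h. This tests the mean over the severe times, so a gene changed at only some of them can pass. The 10 largest rises included the dynein light chain Dynlrb2 (4.38 ± 0.35), the cilia proteins Cfap126 (4.10 ± 0.40), Cfap43 (3.05 ± 0.31) and Enkur (3.03 ± 0.31), the tubulin-binding Tppp3 (3.23 ± 0.33) and Spmip6 (2.98 ± 0.30). Also among them were Bcas1 (3.03 ± 0.37), a gene of early myelinating cells, the interferon-induced Gbp2 (3.99 ± 0.24) and complement factor Cfb (3.07 ± 0.42). The 10 largest falls were in the tendon marker Tnmd (-5.62 ± 0.53), the proteoglycans Aspn (-5.00 ± 0.50), Lum (-4.87 ± 0.70) and Dcn (-4.34 ± 0.67), the collagens Col14a1 (-4.59 ± 0.27) and Col8a1 (-4.41 ± 0.48), smooth-muscle actin Actg2 (-4.75 ± 0.29), the matrix protein Egfl6 (-4.64 ± 0.15), the protease-like Prss35 (-4.37 ± 0.40) and the homeobox gene Alx1 (-4.27 ± 0.29). The limma adjusted p-values were 2.98e-06 for Dynlrb2, 2.41e-07 for Gbp2 and 9.69e-10 for Egfl6. Each of the 19 genes named lay beyond the 3 reference arrays in 12 of 12 severe arrays. They were picked as the largest changes on these same arrays, so this is no independent check. limma passed 3170 features, 1258 higher and 1912 lower (5295 at an unadjusted p under 0.05). With the chip as a block, where the difference to the reference arrays comes from the 3 severe arrays on their chips, it passed 1446 (418 higher and 1028 lower), 1445 of them shared, and all 3170 kept their sign. Centring on the housekeeping genes moved the median of all genes from 0.01 to 0.10 and passed 3195 (1732 higher and 1463 lower). Ribosomal genes, 63 of these 146 genes, fell in the severe arrays themselves, so the centred split is no independent check of direction. Leaving out mild 48 h replicate 1, 2 or 3 gave 2138 (694 higher and 1444 lower), 2116 (759 and 1357) and 2078 (726 and 1352), and leaving out severe 48 h replicate 2 gave 4129 (1919 and 2210).

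In the same average, fibroblast and meningeal genes fell in 13 of 19 members, 15 adjusted over the list alone (median -2.52, camera adjusted p = 2.6e-12; adjusted p = 0.0868 with an estimated correlation). Col1a1 (-3.94 ± 0.32), Col6a1 (-3.36 ± 0.14) and Col5a1 (-3.18 ± 0.19) were among these genes. Ribosomal protein genes fell in 50 of 63, 53 adjusted over the list alone (median -0.70, camera adjusted p = 2.02e-27; adjusted p = 0.317 with an estimated correlation). Rps2 (-1.30 ± 0.14) and Rpl35 (-0.96 ± 0.11) were among these genes. Stress response genes fell in 19 of 38 and rose in 1 (24 and 1 adjusted over the list alone, median -0.56, camera adjusted p = 7.27e-10; adjusted p = 0.317 with an estimated correlation). Trib3 (-2.42 ± 0.10), Xbp1 (-1.24 ± 0.12), which drives the unfolded protein response, and Chac1 (-1.09 ± 0.09), which degrades glutathione, were among these genes. Hypoxia and glycolysis genes fell in 16 of 33 and rose in 3 (20 and 3 adjusted over the list alone, median -0.48, camera adjusted p = 1.3e-07; adjusted p = 0.351 with an estimated correlation). Slc16a3 (-3.23 ± 0.13) and the vessel growth factor Vegfa (-0.83 ± 0.05) were among these genes. Matrix genes fell in 13 of 35 and rose in 4 (16 and 5 adjusted over the list alone, median -0.44, camera adjusted p = 0.00223; adjusted p = 0.351 with an estimated correlation). Adamts1 (-2.50 ± 0.15) and the laminin Lamb1 (-1.96 ± 0.14) were among these genes.

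Astrocyte genes rose in 13 of 24 members, 14 adjusted over the list alone (median 0.41, camera adjusted p = 4.17e-09; adjusted p = 0.317 with an estimated correlation). S100b (2.84 ± 0.24), the glutamate transporter Slc1a3 (1.06 ± 0.09) and the metallothionein Mt3 (1.22 ± 0.12) were among these genes. Oligodendrocyte lineage genes rose in 8 of 19, 11 adjusted over the list alone (median 0.76, camera adjusted p = 1.26e-06; adjusted p = 0.351 with an estimated correlation). The transcription factors Nkx2-2 (2.38 ± 0.28) and Olig1 (1.73 ± 0.16) were among these genes. Interferon and antigen presentation genes rose in 13 of 34, 17 adjusted over the list alone (median 0.51, camera adjusted p = 5.17e-11; adjusted p = 0.351 with an estimated correlation). Psmb8 (1.61 ± 0.16), Psmb9 (1.08 ± 0.13) and the transcription factor Irf1 (1.13 ± 0.11) were among these genes. Antioxidant genes rose in 10 of 38 and fell in 1 (13 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 6.25e-05; adjusted p = 0.444 with an estimated correlation). Gstm1 (2.26 ± 0.24) and Prdx6 (1.38 ± 0.19) were among these genes. Immediate early genes fell in 9 of 31 and rose in 1, the same numbers adjusted over the list alone (median -0.12, camera adjusted p = 0.0209; adjusted p = 0.836 with an estimated correlation). The transcription factors Klf4 (-1.86 ± 0.28) and Klf2 (-1.73 ± 0.06) were among these genes. Axonal cytoskeleton genes fell in 7 of 39, 7 adjusted over the list alone (median -0.15, camera adjusted p = 0.0209; adjusted p = 0.847 with an estimated correlation). The neuronal tubulin Tubb3 (-1.89 ± 0.44) and the intermediate filament Prph (-1.65 ± 0.34) were among these genes. Cholesterol synthesis genes fell in 2 of 29 and rose in 1, the same numbers adjusted over the list alone (median -0.23, camera adjusted p = 0.0356; adjusted p = 0.847 with an estimated correlation). The last 3 lists did not pass with the chip as a block (camera adjusted p = 0.125, 0.103 and 0.103).

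The other 13 lists did not pass in the average at the preset correlation, though single members did. Axon injury and regeneration genes had a median of -0.04, 4 risen and 4 fallen of 35. The chaperone Hspb1 (1.93 ± 0.20) and the injury factor Cntf (2.27 ± 0.31) were higher. The synapse list had a median of -0.10 with 0 risen and 1 fallen of 44. Cytokine, chemokine and NF-kB genes had a median of 0.10, 6 risen and 5 fallen of 37, with Il18 (1.06 ± 0.15) above and the alarmin receptor Il1rl1 (-1.91 ± 0.14) below. Apoptosis genes had a median of 0.00, 3 risen and 7 fallen of 43, with the inflammatory caspase Casp4 (-1.20 ± 0.15). Neurotrophic factor genes had a median of -0.05, 1 risen and 9 fallen of 36, with the growth factor Mdk (-1.45 ± 0.17). Heat shock chaperones had a median of 0.00 (6 risen and 2 fallen of 31), calcium handling -0.11 (1 and 4 of 32) and cell division -0.07 (1 and 2 of 31). Microglia and macrophage genes had a median of 0.00 (1 risen and 1 fallen of 25), endothelial genes 0.00 (0 and 2 of 14) and p53 targets 0.02 (0 and 1 of 23). Oxidative phosphorylation (0.04, 49 genes) and proteasome (0.12, 34 genes) had 0 members past the threshold. For the microglia, endothelial, p53 and heat shock lists, the median and the test differed in sign.

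**Figure D2:**
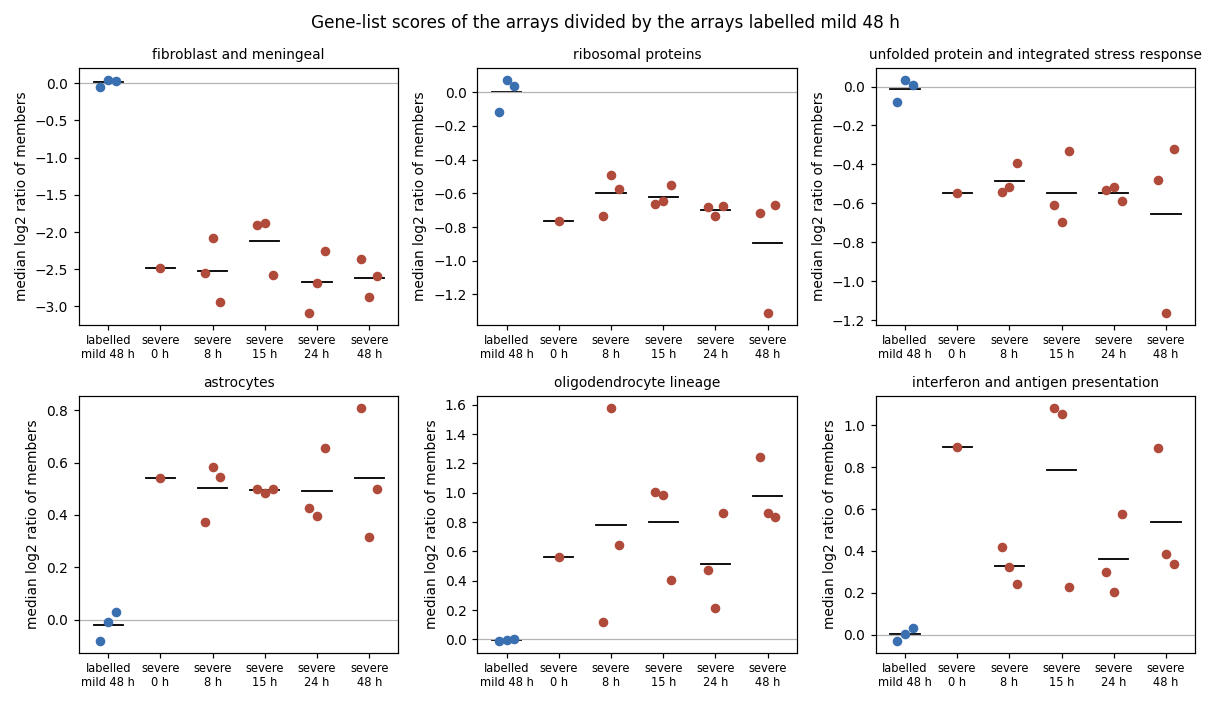
Median log2 ratio of the members of 6 gene lists (vertical axes) in the 3 arrays labelled mild 48 h (blue), the 1 severe 0 h array and the 3 severe arrays at each of 8, 15, 24 and 48 h (red). Dots are arrays and lines are group means; the fibroblast and meningeal list lies between -3.09 and -1.87 in the 12 severe arrays at 8 to 48 h and between -0.05 and 0.05 in the 3 reference arrays.

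Single severe times were set against the same 3 reference arrays, so these comparisons and the average are not independent. At 8 h Dynlrb2 rose by 4.39 ± 0.44, Gbp2 by 4.14 ± 0.30 and Cfap126 by 4.09 ± 0.50, while Tnmd was at -6.14 ± 0.67, Lum at -5.59 ± 0.89 and Aspn at -5.39 ± 0.63. At 15 h the largest rises were in Dynlrb2 (4.59 ± 0.44), Cfap126 (4.45 ± 0.50) and Gbp2 (4.33 ± 0.30), and the largest falls in Tnmd (-5.24 ± 0.67), Actg2 (-4.79 ± 0.37) and Egfl6 (-4.49 ± 0.19). At 24 h they were in Dynlrb2 (4.05 ± 0.44), Gbp2 (3.81 ± 0.30) and Cfap126 (3.66 ± 0.50), and in Tnmd (-5.54 ± 0.67), Lum (-5.23 ± 0.89) and Aspn (-5.13 ± 0.63). The ratio of Lum in severe 8 h replicate 1 stands at the smallest value of the table, 0.01, so its fall at 8 h may be understated. limma passed 1882 features at 8 h (759 higher and 1123 lower), 2368 at 15 h (970 and 1398) and 2011 at 24 h (623 and 1388), with 3 arrays each. Centring on the housekeeping genes gave 2021 (998 higher and 1023 lower), 2459 (1381 and 1078, the larger number then being higher) and 2191 (998 and 1193). The ribosomal genes among them fell in the severe average, so these splits are no independent check of direction. With the chip as a block limma passed 812, 965 and 907, and with all 34 arrays in the fit 3057, 3797 and 3320. With only the compared arrays it passed 3104 at 8 h (1562 higher and 1542 lower) and 3983 at 15 h, and with quantile normalization 1418 at 15 h. Without mild 48 h replicate 3 the counts were 1169, 1571 and 1307, and without mild 48 h replicate 2 they were 1191 at 8 h and 1327 at 24 h. Without severe 8 h replicate 3 the count at 8 h was 1252. The number higher fell by more than 1.5 times without mild 48 h replicate 1, to 393, 577 and 322 at 8, 15 and 24 h. It also did so without severe 8 h replicate 2 (474), mild 48 h replicate 2 and severe 15 h replicate 1 or 2 (618, 604 and 643 at 15 h), and severe 24 h replicate 1 or 3 (336 and 372). Whether the 4 severe times differed was tested with the severe time course, in which limma passed 0 features with and without the chip as a block (808 at an unadjusted p under 0.05).

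In the arrays labelled mild 0 to 24 h against all 6 arrays labelled control, limma passed 0 features at 0, 8, 15 and 24 h (567, 693, 1231 and 787 at an unadjusted p under 0.05; 3 arrays each), with and without the chip as a block. The 6 controls were fitted here as 1 group, although limma passed 2587 features between control 4 to 6 and control 1 to 3. The spread was that of all 34 arrays, the severe ones included. These counts of 0 therefore do not show that no gene changed. The values that follow are those of list members with the smallest p-values, none past the threshold over all genes. At 8 h the chemokine Ccl20 was at 3.17 ± 0.79 and the acute-phase protein Lcn2 at 2.69 ± 0.75, with the chemokine Ccl4 at 0.50 ± 0.16, the NF-kB subunit Nfkb2 at 0.48 ± 0.14 and the Fc receptor Fcgr3a at 1.15 ± 0.33. At 0 h Ccl20 was at 2.16 ± 0.79, Lcn2 at 1.84 ± 0.75 and Il1rl1 at 0.78 ± 0.19. At 15 h the metallothionein Mt1 was at 0.89 ± 0.17 (adjusted p = 0.156), Hspb1 at 0.86 ± 0.20 and the activity-induced Npas4 at 0.49 ± 0.12. At 24 h Mt1 was at 0.65 ± 0.17 and Npas4 at 0.34 ± 0.12. With only the compared arrays fitted, 10 features passed at 8 h. Single arrays gave a few calls: 2 at 8 h without mild 8 h replicate 2, and 3 at 15 h and 1 at 24 h without control replicate 2.

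By list against all 6 controls at 8 h, camera at the preset correlation put cytokine, chemokine and NF-kB genes past the threshold (median 0.15, camera adjusted p = 1.1e-12; adjusted p = 0.2 with an estimated correlation), with 0 members past over all genes and 5 risen adjusted over the list alone. Microglia and macrophage genes also passed upward at 8 h (median 0.10, camera adjusted p = 1.96e-07; adjusted p = 0.429 with an estimated correlation), with 2 risen adjusted over the list alone. Interferon genes (median 0.10) and ribosomal genes (-0.04) passed as well (adjusted p = 0.998 for both with an estimated correlation). The ribosomal median turned to 0.12 with the replicate number as a block. It was -0.11 without control 2 and -0.0045 without control 5, and the list did not pass without control 3, 4, 5 or 6 or mild 8 h replicate 2 or 3. At 15 h cell division genes passed downward (median -0.37, camera adjusted p = 4.46e-12; adjusted p = 0.696 with an estimated correlation) and immediate early genes upward (median 0.23, camera adjusted p = 3.69e-11; adjusted p = 0.412 with an estimated correlation), the latter with 2 risen adjusted over the list alone. Control 4 to 6 were low in immediate early genes such as Egr1 (-1.68 to -1.42) and high in cell division genes against control 1 to 3. Egr1 lay between -0.14 and 0.18 in the mild 15 and 24 h arrays. These calls, and that of immediate early genes at 24 h, may thus come in part from control 4 to 6. Proteasome genes had a median of -0.23 and oxidative phosphorylation genes -0.16, both past at the preset correlation (adjusted p = 0.834 and 0.84 with an estimated correlation). With the replicate number as a block the oxidative phosphorylation median turned to 0.016. It was -0.28 without mild 15 h replicate 2 and -0.073, not past, without mild 15 h replicate 1. The other 7 lists past at 15 h had medians between -0.13 and 0.12 and adjusted p-values between 0.834 and 0.861 with an estimated correlation. Of these, the stress response and cholesterol medians turned to 0.03 and 0.13 with the replicate number as a block. At 24 h immediate early genes (0.18) and NRF2 targets (0.10) passed upward and microglia (-0.10), cholesterol synthesis (-0.21) and hypoxia genes (-0.09) downward (adjusted p = 0.953 for each with an estimated correlation). At 0 h cholesterol synthesis (0.29), proteasome (0.15), oxidative phosphorylation (0.14) and 4 more lists passed upward (adjusted p = 0.912 for each with an estimated correlation). Centring on the housekeeping genes moved the median of all genes from 0.02 to -0.11 at 0 h and from -0.01 to 0.11 at 15 h. It turned the 0 h medians of ribosomal, axonal, cytokine and stress response genes to between -0.04 and 0.00 and the 15 h median of hypoxia genes to 0.02. Single arrays decided some of these numbers: 0 h had 2 lists without control replicate 2 and 1 without mild 0 h replicate 2, 15 h had 7 without mild 15 h replicate 1 or 3, and 24 h had 8 without control replicate 2.

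Over the mild time course (0, 8, 15 and 24 h, 3 arrays each), limma passed 1 gene in the fit on all 34 arrays. That fit uses 1 spread, which takes in the severe arrays and the 6 controls as 1 group. Genes can therefore differ between the mild times without passing. Egr1 did not pass. It lay between -1.56 and -1.16 in the mild 0 and 8 h arrays and between -0.14 and 0.18 at 15 and 24 h. Adh1c, an alcohol dehydrogenase, had group means of -0.30 ± 0.15 (SD) at 0 h, -0.18 ± 0.06 at 8 h, 0.33 ± 0.11 at 15 h and 0.25 ± 0.12 at 24 h (limma F test, adjusted p = 0.0379; 1093 features at an unadjusted p under 0.05). With the chip as a block its adjusted p was 0.18, and leaving out any 1 of the 12 arrays other than mild 0 h replicate 2 and mild 24 h replicate 1 ended the call, with 0 genes. With only the compared arrays fitted, 339 features passed (3126 at an unadjusted p under 0.05), with the replicate number as a block 6, and with quantile normalization, housekeeping centring or the 18 arrays of 1 divisor 0. Whether the severe by mild difference changed between 8, 15 and 24 h was tested by limma as well, and 0 features passed (994 at an unadjusted p under 0.05). Without severe 15 h replicate 3 there were 7, and without mild 15 h replicate 3 or severe 24 h replicate 2 there was 1.

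The 6 controls differ in their place in the divisor, so control 4 to 6 were set against control 1 to 3, 3 arrays each. The immediate early transcription factors Egr1 and Fos, induced by neuronal activity, fell, at -1.50 ± 0.12 (adjusted p = 8.25e-06) and -1.41 ± 0.14, in 3 of 3 arrays. These calls also passed with the chip as a block, as did that of the nuclear import gene Kpna1, but chip 3 holds only control 5 and 6 of the 18 arrays, so the blocked values rest on control 4 alone. Kpna1 rose by 0.82 ± 0.10. Past the threshold without the block alone were the desaturase Scd (1.40 ± 0.35), the complement gene C1qb (1.16 ± 0.31) and the matricellular gene Ccn1 (-0.83 ± 0.13). limma passed 2587 features, 2519 higher and 68 lower (5654 at an unadjusted p under 0.05). With the chip as a block it passed 6. Chip 2 alone again holds only control 4 of control 4 to 6, so no count is given for it. With quantile normalization limma passed 18 (8 higher and 10 lower), and with all 34 arrays in the fit 6. Centring on the housekeeping genes moved the median of all genes from 0.04 to -0.31 and passed 12335, with 137 higher and 12198 lower. Leaving out control 2 gave 122, control 4 1426, control 5 655 and control 6 627, and the number lower was 43 without control 1 and 107 without control 3.

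By list, immediate early genes fell in 8 of 31 members, 9 adjusted over the list alone (median -0.13, camera adjusted p = 1.14e-11; adjusted p = 0.289 with an estimated correlation). Egr4 (-0.48 ± 0.07) and Arc (-0.44 ± 0.08) were among these genes. Cholesterol synthesis genes rose in 20 of 29, 24 adjusted over the list alone (median 0.66, camera adjusted p = 2.03e-09; adjusted p = 0.425 with an estimated correlation). Fdps (0.88 ± 0.15), Hmgcs1 (0.66 ± 0.12) and Dhcr7 (0.80 ± 0.16) were among these genes. Oxidative phosphorylation genes rose in 32 of 49, 44 adjusted over the list alone (median 0.39, camera adjusted p = 1.96e-14; adjusted p = 0.425 with an estimated correlation), and proteasome genes in 22 of 34 (31 risen and 1 fallen adjusted over the list alone; median 0.38, camera adjusted p = 6.55e-12; adjusted p = 0.425 with an estimated correlation). Ribosomal protein genes rose in 18 of 63, 48 adjusted over the list alone (median 0.30, camera adjusted p = 1.82e-10; adjusted p = 0.499 with an estimated correlation). Cell division genes rose in 14 of 31, 23 adjusted over the list alone (median 0.46, camera adjusted p = 1.5e-08; adjusted p = 0.425 with an estimated correlation). The remaining 7 lists past the threshold had medians between 0.17 and 0.34 and adjusted p-values between 0.425 and 0.742 with an estimated correlation. Housekeeping centring turned the medians of the ribosomal, axonal, fibroblast, apoptosis, heat shock, NRF2 and hypoxia lists to between -0.18 and -0.02. Microglia and macrophage genes, not past as a list, rose in 8 of 25 members, with the complement gene C1qc (1.11 ± 0.26) and the lysosomal Cd68 (1.09 ± 0.26) (list median 0.17).

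**Figure D3:**
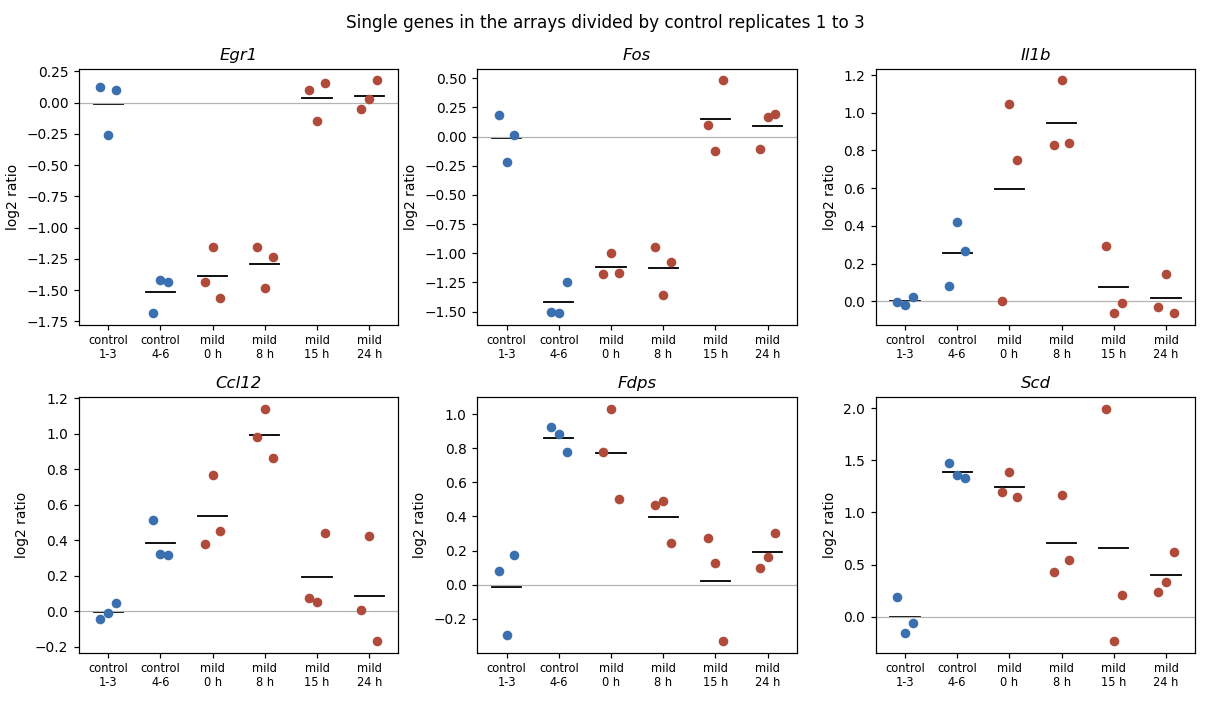
Log2 ratio of Egr1, Fos, Il1b, Ccl12, Fdps and Scd (vertical axes) in control 1 to 3, control 4 to 6 (blue) and mild 0, 8, 15 and 24 h (red), 3 arrays per group, dots being arrays and lines group means. Egr1 averages -1.51 in control 4 to 6, -1.39 at mild 0 h and -1.29 at mild 8 h, and 0.04 at mild 15 h.

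The mild arrays were also set against control 1 to 3 alone, 3 arrays each. At 8 h Rac2, a GTPase of blood cells, rose by 1.24 ± 0.18 (adjusted p = 0.00763), the chemokine Ccl12 by 1.00 ± 0.14, the leukocyte actin bundler Lcp1 by 0.98 ± 0.15, the interleukin Il1b by 0.95 ± 0.18 and Fcgr3a by 1.62 ± 0.28. Egr1, Fos and Egr2 fell, at -1.28 ± 0.12, -1.12 ± 0.14 and -0.76 ± 0.11. At 0 h the rises were led by Il1rl1 (1.00 ± 0.20), Kpna1 (0.81 ± 0.10) and Fdps (0.78 ± 0.15) and the falls by Egr1 (-1.38 ± 0.12), Fos (-1.11 ± 0.14) and the matricellular Ccn2 (-0.89 ± 0.16). Control 4 to 6, set against the same arrays, had group means of 0.26 ± 0.17 (SD) for Il1b, 0.39 ± 0.11 for Ccl12, 0.52 ± 0.13 for Rac2 and -1.51 ± 0.15 for Egr1. The mild 8 h means were 0.95 ± 0.19, 1.00 ± 0.14, 1.24 ± 0.09 and -1.29 ± 0.17. All these comparisons share control 1 to 3, and mild 8 h was not tested against control 4 to 6 alone. limma passed 1046 features at 0 h (1010 higher and 36 lower), 26 at 8 h (19 and 7), and 0 at 15 and 24 h (1155 and 1913 at an unadjusted p under 0.05). With the chip as a block it passed 163, 7, 0 and 0. At 0 h it passed 34 (23 higher and 11 lower) with quantile normalization, 8 with only the compared arrays, 6 with the replicate block and 1 with all 34 arrays. At 8 h these gave 36, 169, 3 and 0. Centring on the housekeeping genes moved the median of all genes from 0.03 to -0.27 at 0 h, with 7853 passed (74 higher and 7779 lower), from 0.02 to -0.11 at 8 h, with 32 passed (10 higher and 22 lower), and from 0.04 to -0.14 at 24 h.

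Every array of the 0 and 8 h comparisons with control 1 to 3 moved the count by more than 1.5 times. At 0 h it was 541, 49 and 1663 without control 1, 2 and 3, and 124, 11 and 2372 without mild 0 h replicate 1, 2 and 3. At 8 h it was 4, 12 and 3 without control 1, 2 and 3, and 6, 14 and 6 without mild 8 h replicate 1, 2 and 3. At 15 h it was 1 without control 2. By list at 8 h, cytokine, chemokine and NF-kB genes rose in 2 of 37 members, 16 adjusted over the list alone (median 0.35, camera adjusted p = 4.23e-10; adjusted p = 0.314 with an estimated correlation), and microglia and macrophage genes in 1 of 25, 13 adjusted over the list alone (median 0.22, camera adjusted p = 1.44e-08; adjusted p = 0.225 with an estimated correlation). Immediate early genes fell in 4 of 31 (9 fallen and 1 risen adjusted over the list alone; median -0.11, camera adjusted p = 1.78e-11; adjusted p = 0.225 with an estimated correlation). At 0 h immediate early genes fell in 6, 8 adjusted over the list alone (median -0.11, camera adjusted p = 2.3e-08; adjusted p = 0.432 with an estimated correlation). Cholesterol synthesis genes rose at 0 h in 16 of 29, 23 adjusted over the list alone (median 0.63, camera adjusted p = 2.19e-11; adjusted p = 0.432 with an estimated correlation). Oxidative phosphorylation genes rose at 0 h in 10 of 49, 37 adjusted over the list alone (median 0.33, camera adjusted p = 3.03e-13; adjusted p = 0.432 with an estimated correlation). At 15 h NRF2 targets (0.18) and cytokine genes (0.17) passed upward and cell division genes (-0.16) downward (adjusted p = 0.508, 0.508 and 0.568 with an estimated correlation). At 24 h NRF2 targets (0.23) and oxidative phosphorylation genes (0.20) passed upward and microglia genes (-0.09) downward (adjusted p = 0.637 for each with an estimated correlation). In all, 13, 13, 10 and 12 lists passed at 0, 8, 15 and 24 h at the preset correlation and 0 with an estimated correlation. Without control 2 the counts were 8 at 8 h and 5 at 24 h.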

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

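The tests of the chip, of a lower share of neurons and of responses that build up with time were chosen after the result was seen, as were the comparisons with the arrays labelled mild 48 h at other times and with control 1 to 3.

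The 1 severe 0 h array entered no comparison, and 4 list scores in it (median log2 ratio of the members) lay above all 3 arrays labelled mild 48 h. These were astrocytes at 0.541, oligodendrocyte lineage at 0.559, interferon and antigen presentation at 0.897 and antioxidant and NRF2 targets at 0.38. Of the 3170 genes called in the severe average, 3161 (99.7%) lay on the same side in that array, with a median of 0.765 over the risen genes against 0.71 in the average and -0.757 over the fallen genes against -0.668. Below all 3 reference arrays lay 1894 of the 1912 fallen genes, and the fibroblast and meningeal list was at -2.48. Both are ratios to the same 3 arrays, which alone puts part of the genes on 1 side, and no value without these arrays was computed.

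The first pattern was lower fibroblast and meningeal genes together with higher astrocyte and oligodendrocyte lineage genes in the severe arrays. The 3 pairs of a severe and a reference array labelled as on 1 chip had a median of -0.672 over the fallen genes and 0.71 over the risen ones. If the labels hold, these values argued against the chip, although the genes were called on these same arrays. In the other order of labels the reference values would belong to arrays of chips 2 and 3, and the pairs could not decide. The tables argued against a lower share of neurons alone, under which the fibroblast and glial lists would move the same way. The fibroblast and meningeal list lay below and the astrocyte list above all 3 reference arrays in 12 of 12 severe arrays. A lower share of fibroblast or meningeal cells would give this pattern too, so the test cannot decide on it. Of the 19 and 24 genes of these lists, another list holds 2 each, and ratios give no levels of their most abundant genes. The list scores argued against a build-up from 8 to 48 h of the fibroblast fall (8 h mean -2.52 ± 0.43 (SD), array nearest 0 at -2.08, 48 h mean -2.61) and of the astrocyte rise (0.50 ± 0.11, 0.374, 0.54). Other differences in cell composition between cultures and the injury itself may still account for the pattern. A build-up of the oligodendrocyte rise (8 h array nearest 0 at 0.12) cannot be told apart from these. Nor can mislabelled reference arrays (mean correlation of 0.0215, where mild groups do not correlate by number among themselves). A build-up before 8 h would leave the difference small at 0 h. The severe 0 h array was already at 0.765 over the risen genes, against 0.71 in the average. As 1 array it cannot decide, so a build-up before 8 h stays open.

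The second pattern was the small rise of many genes in control 4 to 6 over control 1 to 3 (2519 higher and 68 lower, but 8 higher and 10 lower with quantile normalization). The chip cannot be told apart from this difference, since with the chip as a block the median of the 2519 risen genes (0.413, from 0.409; median SE 0.153, from 0.104) rests on control 4 alone, control 5 and 6 being the only arrays of the 18 on chip 3. With the housekeeping median of each array as a covariate, the median over the 2447 risen genes outside those lists went from 0.409 (SE 0.104) to 0.154 (SE 0.112). A shift shared with the housekeeping genes may thus account for most of the size. Each ratio was already divided by the array's median, and the housekeeping median was itself higher in control 4 to 6. The covariate therefore cannot tell a technical shift from a real one. Displaced labels in the deposited table cannot be told from a real difference between controls (mean correlation with mild replicates -0.0345), since the mild groups do not correlate by number. No biological explanation was tested, because the labels give the controls no difference.

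The third pattern was the fall of 8 immediate early genes in the same control 4 to 6. A shift shared with the housekeeping genes was argued against by direction alone, since the housekeeping median was higher in control 4 to 6 and these genes were lower. With the housekeeping covariate the median of the 8 genes went from -0.555 (SE 0.115) to -0.846 (SE 0.132). The 8 genes were chosen for their fall, so the covariate adds little to the direction. In that fit 6 genes passed, all lower: Akr1c19, Ccn1, Dusp6, Egr1, Egr2 and Fos. Egr1 averaged -1.51 ± 0.15 (SD) in control 4 to 6, -1.39 ± 0.21 at mild 0 h and -1.29 ± 0.17 at mild 8 h, against -0.01 ± 0.21 in control 1 to 3 and 0.04 ± 0.16 at mild 15 h. Displaced labels (-0.0345) may underlie this and stay open, and no biological explanation was tested, since the labels give the controls no difference.

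Other splits of the same arrays were counted for each comparison. For the severe average, 1 of 100 splits, the real one, gave as many as 3170 features, and the highest other gave 769. That highest split put replicate 3 of severe 8, 15 and 48 h together, which points to a structure of the severe arrays, and the average passed 3180 with the replicate number as a block. The splits thus argue against a random grouping only if the arrays are independent. The comparison was chosen after seeing the data, and 3 cultures were used, so a difference between cultures is not excluded. For the mild time course 2 of 100 splits gave as many (1 gene; highest other 1), so a random split equalled the real one, and the call ended with the chip as a block and in 10 of 12 fits without 1 array. Where limma passed 0, every split gives as many by construction, so the splits say nothing about chance: this held for mild 0, 8, 15 and 24 h against all 6 controls (84 of 84), the severe by mild difference (100 of 100) and the severe time course (100 of 100). The highest others were 31, 3, 141 and 16 for the mild times. They put control 1 to 3 together at 0 and 8 h and control 4 to 6 together at 15 and 24 h, which points to a structure of the controls. For the severe by mild difference and the severe time course the highest others were 539 and 879, which point to a structure of the samples too. With 3 arrays against 3, 10 splits are too few to tell. The real counts were 3731 at 48 h, 1882, 2368 and 2011 for severe 8, 15 and 24 h, 2587 for control 4 to 6, and 1046, 26, 0 and 0 for mild 0, 8, 15 and 24 h against control 1 to 3, with a highest other of 0 in each.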

How the results depend on the processing

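Chosen after seeing the data were quantile normalization of the ratios, housekeeping centring and covariate, the fits on 1 divisor set or all 34 arrays for added comparisons, same-chip pairs, and every alternative of an added comparison. Counts of features are those of limma. The severe average stayed within 1.5 times of 3170 with quantile normalization (2122), housekeeping centring (3195), all 34 arrays (4499) and 3 same-chip pairs (2811), and none of its lists or named genes reversed under the alternatives run for them. The chip block gave 0 for the mild time course, 812, 965, 907 and 1446 for severe 8, 15, 24 h and average, 6 for control 4 to 6, and 163 and 7 for mild 0 and 8 h against control 1 to 3; for control 4 to 6 the blocked value rests on control 4 alone, with larger standard errors, and elsewhere the cause was not tested. The labels do not tie replicate numbers to cultures, and same-numbered arrays of mild 0 to 24 h did not deviate together (mean correlation -0.0488). In 4 of 55 pairs of groups every same-numbered correlation was over 0.1: severe 15 with 48 h (mean 0.506), control 1 to 3 with severe 48 h (0.349), and mild 24 h with severe 15 h (0.296) and 8 h (0.222). Pairing between some groups thus remains possible. The replicate block gave 3180 for the severe average, 0 for the severe time course (708 at an unadjusted p under 0.05), 6 for the mild time course, and 6 and 3 for mild 0 and 8 h against control 1 to 3. With it, 12 lists passed at mild 0 h and 12 at mild 8 h against control, since control 4 to 6 then sit alone in their blocks, and 4 lists reversed against control: ribosomal at 8 h (0.12), and stress response (0.027), cholesterol (0.13) and oxidative phosphorylation (0.016) at 15 h; it moved no other count past 1.5 times. Fits with only the compared arrays gave 10 for mild 8 h against control, 1481 for severe against mild at 48 h, 339 for the mild time course, 1 for the severe by mild difference, 3104 and 3983 for severe 8 and 15 h, 8 and 169 for mild 0 and 8 h against control 1 to 3, and 8 lists at mild 24 h. Fits on 1 divisor set gave 2453 at 48 h and 0 for the mild time course, and fits on all 34 arrays 3057, 3797 and 3320 for severe 8, 15 and 24 h, 6 for control 4 to 6, and 1 and 0 for mild 0 and 8 h against control 1 to 3. Within chip 2, mild 0 h, mild 8 h and control 4 to 6 had 1 array each, so counts from these fits are not given. Quantile normalization gave 2157 at 48 h, 0 for the mild time course, 1418 at severe 15 h, 18 (8 higher, 10 lower) for control 4 to 6 and 34 (23 higher, 11 lower) for mild 0 h against control 1 to 3. Housekeeping centring gave 0 for the mild time course, 12335 for control 4 to 6, 7853 for mild 0 h against control 1 to 3, and 13 and 12 lists at mild 0 and 24 h against control; the housekeeping covariate gave 6 for control 4 to 6. With centring 5 named genes reversed in control 4 to 6: Dctn1 (-0.015), Sod1 (-0.042), Egln1 (-0.039), Gpi (-0.049) and Egfr (-0.058). The chip block left 7 lists at mild 15 h. With an estimated correlation 1 list passed at severe against mild 48 h and 0 in the other 10 comparisons with list tests, so 113 of 114 list calls ended. Leaving out each array in turn gave 0 to 0, 0 to 2, 0 to 3 and 0 to 1 for mild 0, 8, 15 and 24 h against control, 2964 to 4844 at 48 h, 0 to 1 for the mild time course, 0 to 7 for the severe by mild difference, 1169 to 1518, 1571 to 2061, 1307 to 1991 and 2078 to 4129 for severe 8, 15, 24 h and average, 0 to 0 for the severe time course, 122 to 3413 for control 4 to 6, and 11 to 2372, 3 to 14, 0 to 1 and 0 to 0 for mild 0, 8, 15 and 24 h against control 1 to 3. Lists ranged over 11 to 13 for the severe average, 14 to 19 at 48 h, 1 to 9, 3 to 6, 7 to 13 and 4 to 8 at mild 0, 8, 15 and 24 h, 10 to 13 for control 4 to 6, and 10 to 15, 8 to 15, 9 to 13 and 5 to 12 for mild 0, 8, 15 and 24 h against control 1 to 3. For 3 of the lists that the replicate block reversed, leaving out 1 array gave -0.109 to -0.0045 (ribosomal, mild 8 h), -0.174 to -0.0816 (stress response, mild 15 h) and -0.278 to -0.0732 (oxidative phosphorylation, mild 15 h). A list reversed in 3 of these fits. At mild 15 h, NRF2 targets ranged from -0.031 (reversed, without mild 15 h replicate 1) to 0.085, and cholesterol from -0.396 to -0.036 (reversed by the test, without mild 15 h replicate 3). Ribosomal genes at mild 8 h against control 1 to 3 ranged from 0.0049 (reversed by the test, without control 2) to 0.193. Where not stated, the cause was not tested. Among named genes, the chip block left 952 values on their side of the threshold, made 150 weaker and 2 stronger, and leaving out 1 array left 8272, made 450 weaker and 62 stronger. Not run, since ratios lack signal levels, were no background correction, median scaling of signals and a stricter or no detection filter; a comparison within a chip was impossible for severe against mild at 48 h. Signal over background is unknown, so what it limits is unknown.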

Other observations

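The test of a cilia list was chosen after cilia genes were seen among the largest rises of the severe average, and the genes already named were left out of it. Genes of motile cilia were higher in the severe arrays than in the 3 arrays labelled mild 48 h: 18 of 26 list members rose and 0 fell, with a median log2 difference of 0.69. Examples were Drc3 (2.09 ± 0.25) and Drc1 (1.72 ± 0.24), parts of the complex that regulates axonemal dynein, Dnah11 (1.37 ± 0.17), a dynein heavy chain, and Ccno (1.93 ± 0.27), needed to form many cilia per cell. The list score lay between 0.236 and 1.25 in the 12 severe arrays at 8 to 48 h, at 0.758 in the severe 0 h array and between -0.0234 and 0.0179 in the reference arrays. The hypothesis that the list moved as a whole did not meet the prediction set for it: camera gave an adjusted p of 3.05e-14 at the preset correlation and 0.264 with an estimated correlation.

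In the mild arrays, Ccl20 and Lcn2 differed widely between arrays of 1 group at 0 and 15 h, and less so at 8 and 24 h. Ccl20 averaged 2.59 ± 1.52 (SD, n = 3) at 0 h, 3.60 ± 0.20 at 8 h, 1.54 ± 2.26 at 15 h and 0.09 ± 0.21 at 24 h, with 0.87 ± 0.59 in control 4 to 6. Lcn2 averaged 1.96 ± 1.24, 2.82 ± 0.48, 1.46 ± 2.25 and 0.02 ± 0.09, with 0.26 ± 0.24 in control 4 to 6.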
